A study of Mus musculus with 8 samples.

How the data were processed

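Gene expression was measured by RNA sequencing of embryonic mouse lung at E13.5. The 8 libraries comprised 4 from cre controls and 4 from mutants, which carried the transgene combination that the labels write as Tbx4tetOcre together with the Myrf allele written as MyrfE6. The labels do not explain the allele, do not give the sex or number of embryos in a library and do not say whether the 4 libraries of a group came from separate litters, so p-values measure only the spread between these libraries. Per the labels' protocols, RNA was isolated with TRIzol LS, purified on a Qiagen micro kit and made into libraries with a stranded Illumina kit that selects messenger RNA.

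The authors deposited 1 table of raw counts, whole numbers of read pairs per gene with no normalization and 1 column per library. Per the file headers, the counts were made with featureCounts 1.6.4 in paired-end mode, with strand option 2 (reads from the reverse strand), by summing exons per gene of the GENCODE vM25 annotation. Neither the option that keeps reads mapping to several places nor the one that keeps reads overlapping several genes was set, per the file headers, so reads shared between near-identical genes or overlapping exons on the same strand were not counted. The submitters' processing notes name STAR, featureCounts, DESeq2 and the genome build GRCm38 (mm10); the version of STAR is not given in the sources used here. Gene coordinates are those of the deposited table, on GRCm38, and run from the first to the last exon base of the gene. The deposited table also gives an exon length in bases per gene, which was used only to compare genes by length.

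The table held 55401 genes, of which 55141 were paired with a symbol and 260 were not. Gene types came from the GENCODE vM21 annotation of the same genome build. Total counts ranged from 17799899 to 48679134 per library, and up to 19032389 in the controls. At the smallest total, 3 counts correspond to 0.169 CPM (counts per M counts, with M for mega), a floor that covers counting error only.

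All 8 libraries entered one fit in edgeR 4.0.16 under R 4.3.3. Genes with too few counts were removed with the package's expression filter, which left 15788 genes holding 99.9% of the counts. Libraries were scaled by trimmed means of M-values (TMM), dispersions were estimated robustly, and mutant was compared with control by the two-sided quasi-likelihood F test, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Fold changes are mutant over control, standard errors (SE) belong to the log2 fold change, and CPM values are TMM-scaled means ± SD over 4 libraries unless a single library is named. Levels of Xist and of the 4 Y-linked genes are CPM of all counts, without TMM scaling.

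Before the data were examined, 32 gene lists were fixed, covering cell types of the lung and its neighbours, signalling pathways and cell states. The listed name Ero1a was read as Ero1l, and 1 listed gene, Ahsp, was absent from the table. The lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 32 lists, each with at least 5 tested genes. Beside it stand camera with an estimated correlation and fry, whose directional p asks whether the genes of a list move one way on balance. Members of a list were also adjusted over the list alone.

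Most genes named in the text followed a rule fixed before the data were examined. It took Myrf, then the 10 largest rises and 10 largest falls among changed genes with a mean log2 CPM of at least 1 and groups that did not overlap, leaving out provisional names. It also took up to 10 changed members of the mesothelium list, up to 3 of every other list and, where no member changed, the 2 members with the highest expression. Further list members named for their values, such as Col4a1, Col4a2 and Col4a5, were chosen after their values were seen. So were the genes outside the lists and the rule (Aldh1a7, Hoxa6, Hoxb5, Epha3, Sema3a, Sema3d, Unc5b, Peg10, Asb4, Foxa1, Cftr and Bmp3). The result for 1 gene taken by the rule is not reported here.

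The steps were tested on simulated counts for the 15788 genes, in 5 simulations with 200 changed genes each. For the comparison of mutant with control, 58.2% of genes changed 1.25-fold, 70.5% of those changed 1.5-fold and 90.0% of those changed 2-fold were recovered. Of the calls, 6.43% were false. A list of changed genes was called in 5 of 5 simulations, and 1 of 95 lists of unchanged genes was called. The simulated genes varied independently of each other, so these counts do not cover lists whose genes vary together. The estimated correlation between genes was 0.194 in the real mesothelium list and 0.542 in the extracellular matrix list. No pair of libraries within a group was a duplicate: their counts differed by 2.92 to 8.45 times the sampling variance.

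Alternatives fixed before the data were examined were 3 other scalings, 2 other count filters, DESeq2 1.42.0, limma-voom with sample quality weights, edgeR without robust estimation, the replicate number as a block, the log2 level of 4 Y-linked genes as a covariate, 1 surrogate variable from sva 3.50.0, removal of X and Y genes or of red blood cell genes, stricter thresholds, and leaving out each library in turn. Alternatives added after the data were seen were the linear level of the Y-linked genes as a covariate, the 4 libraries with both Xist and Y-linked counts alone, and libraries thinned to the smallest total. No gene or library was left out of the main comparison apart from genes below the count filter.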

Results

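RNA was sequenced from embryonic mouse lung at E13.5, from 4 cre control libraries and 4 libraries carrying Tbx4tetOcre and the MyrfE6 allele. Myrf encodes a membrane-bound transcription factor, known from myelinating oligodendrocytes and also expressed in mesothelium, the epithelial layer that covers the lung and lines the body cavity. The series title names the specification, signalling and plasticity of mesothelium as its subject, and the design allows 1 comparison, mutant against control lung. Totals were 19032389, 17847958, 17799899 and 17804975 counts in control replicates 1 to 4, and 25157303, 48679134, 20447353 and 17819285 in mutant replicates 1 to 4, so mutant replicate 2 was the deepest library. Mitochondrial genes held 1.601% to 1.81% of the counts and hemoglobin genes 0.228% to 0.282%. On the first principal component, which held 26.7% of the variance, mutant replicate 4 lay at -4.12 beside control replicate 4 at -4.96, while the other mutants lay between 12.5 and 23.9 and the other controls between -17.7 and -14.5.

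Myrf itself was lower in the mutant lung. Its level was 114 ± 5.64 CPM in control and 88.4 ± 4.17 CPM in mutant libraries (SD, n = 4), a fall of 22.6% with a log2 fold change of -0.37 (SE 0.044, adjusted p = 0.000211, edgeR quasi-likelihood test). Every mutant library lay between 84.4 and 92.4 CPM, below all controls, which lay between 107 and 120.5 CPM. Myrf (ENSMUSG00000036098.15) lies on chromosome 19 from 10208272 to 10240748 on the minus strand. The values sum all exons of the gene, so they do not show whether an exon is missing from the remaining transcripts.

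Across the genome, 236 of 15788 genes changed, with 89 higher and 147 lower in the mutant lung (edgeR, adjusted p below 0.05), and 216 of them were protein-coding. Most changes were small: the median size was 0.33 on the log2 scale, 60 genes changed at least 1.5-fold and 19 at least 2-fold. Control and mutant libraries did not overlap in 1164 of all 15788 tested genes, 7.37%, where chance gives 2.86% for 4 against 4. The count of 236 changed genes depended on single libraries: it was 100, 121 and 96 without control replicates 1, 2 and 3, 118 without mutant replicate 2 and 479 without mutant replicate 4. Each of these fits had fewer samples. All 236 genes kept the sign of their log2 fold change without each library in turn, in fits that share most libraries with the one that chose them. The count also depended on the method: it was 791 with no low-count filter, 380 with DESeq2, 142 without robust estimation and 96 with 1 surrogate variable. Libraries also differed in sex-linked transcripts, described with the plot of Xist against Y-linked genes, and the count was 68 with the linear level of Y-linked genes as a covariate, chosen after the data were seen. The excess of lower genes turned there, with 39 higher and 29 lower, as it did with the log2 level of the Y-linked genes (53 and 44), in the 4 libraries with both Xist and Y-linked counts (55 and 32) and without control replicate 3 (49 and 47).

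Of 18 tested members of the mesothelium list, 4 fell in the mutant lung and 14 did not pass, 4 of them with positive log2 fold changes; adjusted over the list alone, 7 were lower and 1 higher. Upk3b, which encodes a uroplakin of the mesothelial surface, fell from 88.4 ± 3.49 to 57.0 ± 3.39 CPM, a log2 fold change of -0.63 (SE 0.0465, adjusted p = 1.08e-06), the smallest adjusted p of any gene tested. Wt1, a transcription factor of mesothelium, fell from 19.7 ± 1.52 to 12.2 ± 1.57 CPM (log2 fold change -0.70, SE 0.0898, adjusted p = 0.000424). Gpm6a, a membrane glycoprotein gene, fell from 11.3 ± 1.03 to 6.48 ± 0.709 CPM (log2 fold change -0.80, SE 0.1, adjusted p = 0.000366). The leucine-rich repeat gene Lrrn4 had a log2 fold change of -0.39 (SE 0.0837, adjusted p = 0.0258). Upk3b lies on chromosome 5 from 136038496 to 136046487, Wt1 on chromosome 2 from 105126529 to 105173616, Gpm6a on chromosome 8 from 54954843 to 55060871 and Lrrn4 on chromosome 2 from 132868305 to 132880891.

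**Figure D1:**
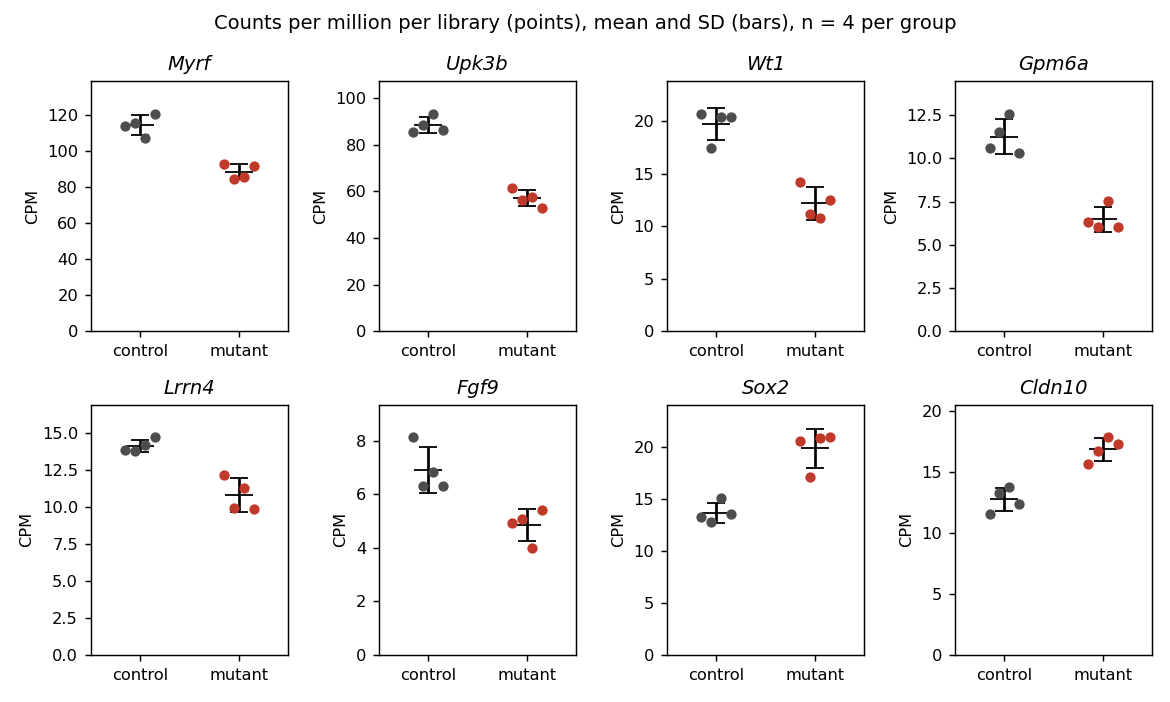
CPM (y axis, from 0) of Myrf, Upk3b, Wt1, Gpm6a, Lrrn4, Fgf9, Sox2 and Cldn10 in each of the 4 control and 4 mutant libraries (points), with the group mean and SD (bars). Upk3b lies at or below 61.2 CPM in mutant and between 85.5 and 93.2 CPM in control libraries.

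Other genes of the mesothelium list did not pass over all genes tested. Aldh1a2, a retinoic acid synthesis gene, measured 84.1 ± 5.66 CPM in control and 63.5 ± 8.86 CPM in mutant libraries (adjusted p = 0.0871), and Calb2 had a log2 fold change of -0.38 (SE 0.0995, adjusted p = 0.0798). Nkain4 measured 50.6 ± 2.99 and 48.0 ± 1.35 CPM (log2 fold change -0.08, SE 0.0486, adjusted p = 0.523). Msln was close to the lowest levels tested, at 0.723 ± 0.173 CPM in control and 0.828 ± 0.315 CPM in mutant libraries. The list as a whole was lower with camera at the preset correlation (adjusted p = 0.000115) but not with an estimated correlation (adjusted p = 0.26), and fry gave an adjusted p of 0.0291. The mean shift of the list against the controls was -0.0467, -0.291, -0.224 and -0.342 in mutant replicates 1 to 4, so mutant replicate 1 lay within the control range of -0.0635 to 0.108. The call of Lrrn4 was lost in 8 of 24 alternatives, and that of Gpm6a in the 4 libraries with both Xist and Y-linked counts.

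Of 15 tested targets and ligands of fibroblast growth factor (FGF) signalling, 5 fell and 10 did not pass, 4 of them with positive log2 fold changes; adjusted over the list alone, 8 were lower and 1 higher. Spry2, an inhibitor of the pathway that is induced by it, fell from 33.9 ± 1.74 to 26.9 ± 1.28 CPM (log2 fold change -0.33, SE 0.0578, adjusted p = 0.00662). The transcription factor genes Etv4 and Etv5, which the pathway induces, had log2 fold changes of -0.31 (SE 0.0651, adjusted p = 0.0252) and -0.18 (SE 0.0368, adjusted p = 0.021). The remaining 2, chosen after their values were seen, were Fgf9, a ligand made by mesothelium and epithelium, at -0.50 (SE 0.122, adjusted p = 0.0473), and Spred1 at -0.19 (SE 0.0443, adjusted p = 0.038). The calls of Fgf9 and Spred1 were not followed through the alternatives. Fgf10, the mesenchymal ligand, did not pass (log2 fold change -0.24, SE 0.0783, adjusted p = 0.14). With camera the list was lower at the preset correlation (adjusted p = 0.000181) but not with an estimated correlation (adjusted p = 0.25). In the 4 libraries with both Xist and Y-linked counts the list did not pass (adjusted p = 0.0636, with 6.77e-05 to 0.25 over its alternatives), and the calls of Spry2, Etv4 and Etv5 were lost in 3, 5 and 9 of 24 alternatives.

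The WNT and hedgehog lists included 3 genes that fell. Lef1, a transcription factor of the WNT pathway, fell from 47.3 ± 3.45 to 36.0 ± 1.41 CPM (log2 fold change -0.39, SE 0.0553, adjusted p = 0.00105). Wnt2, a ligand of the lung mesenchyme, fell from 115 ± 3.9 to 91.4 ± 8.81 CPM (log2 fold change -0.33, SE 0.0559, adjusted p = 0.00852). They were the 2 changed genes among 19 tested of the WNT list, and 5 passed over the list alone, 4 lower and 1 higher. Ptch1, the hedgehog receptor and a target of the pathway, was the 1 changed gene among 13 tested of the hedgehog list (log2 fold change -0.18, SE 0.0333, adjusted p = 0.0115), and 3 were lower and 1 higher over the list alone. Its call was lost in 4 of 24 alternatives. Neither list passed with camera, at adjusted p = 0.137 for WNT and 0.225 for hedgehog, and the log2 fold changes of Shh and Wnt7b, ligands of the epithelium, were -0.06 (SE 0.058) and 0.00 (SE 0.0336).

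Of 9 tested genes of the proximal airway epithelium, 3 rose and 6 did not pass, 4 of them with negative log2 fold changes; adjusted over the list alone, 4 were higher. Sox2, the transcription factor of the conducting airways, rose from 13.7 ± 0.963 to 19.8 ± 1.86 CPM (log2 fold change 0.53, SE 0.0823, adjusted p = 0.00282). The claudin gene Cldn10 had a log2 fold change of 0.40 (SE 0.077, adjusted p = 0.0139), lost in 1 of 24 alternatives, without control replicate 1. Foxj1, Krt5, Krt15 and Trp63, markers of ciliated and basal cells, had negative log2 fold changes and did not pass. Their values were -0.24 (SE 0.203), -0.74 (SE 1.1), -0.11 (SE 0.141) and -0.01 (SE 0.254). Foxj1, Krt5 and Trp63 were low, at 1.58 ± 0.286, 1.40 ± 2.16 and 0.93 ± 0.219 CPM in control libraries. Sox21 and Scgb3a2 had positive log2 fold changes of 0.40 (SE 0.135) and 0.825 (SE 0.316) and did not pass over all genes tested. With camera the list was higher at the preset correlation (adjusted p = 0.00106) but not with an estimated correlation (adjusted p = 0.26). Its mean shift against the controls was 0.104, 0.402, 0.423 and 0.398 in mutant replicates 1 to 4. Mutant replicate 1 thus lay within the control range of -0.248 to 0.385.

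Genes shared by all epithelium and genes of the distal tips had smaller values. All 12 members of the pan-epithelium list had positive log2 fold changes with a median of 0.12, and 0 passed in edgeR over all genes tested, 6 at an unadjusted p below 0.05, 3 over the list alone, and 0 with DESeq2 or limma-voom. Cldn6 measured 192.9 ± 1.54 CPM in control and 203.4 ± 5.11 CPM in mutant libraries, and Epcam 185.5 ± 3.71 and 189.5 ± 2.37 CPM. The list was higher with camera at the preset correlation (adjusted p = 0.000115) but not with an estimated correlation (adjusted p = 0.25). Of 14 tested members of the distal epithelium list, 1 fell, Etv5, which is also an FGF target; 2 were lower over the list alone, and the list did not pass (median log2 fold change -0.07, camera adjusted p = 0.225). Sox9, a transcription factor of the tips, had a log2 fold change of -0.15 (SE 0.071, adjusted p = 0.378), and Sftpc, a surfactant gene, -0.07 (SE 0.103, adjusted p = 0.826).

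**Figure D2:**
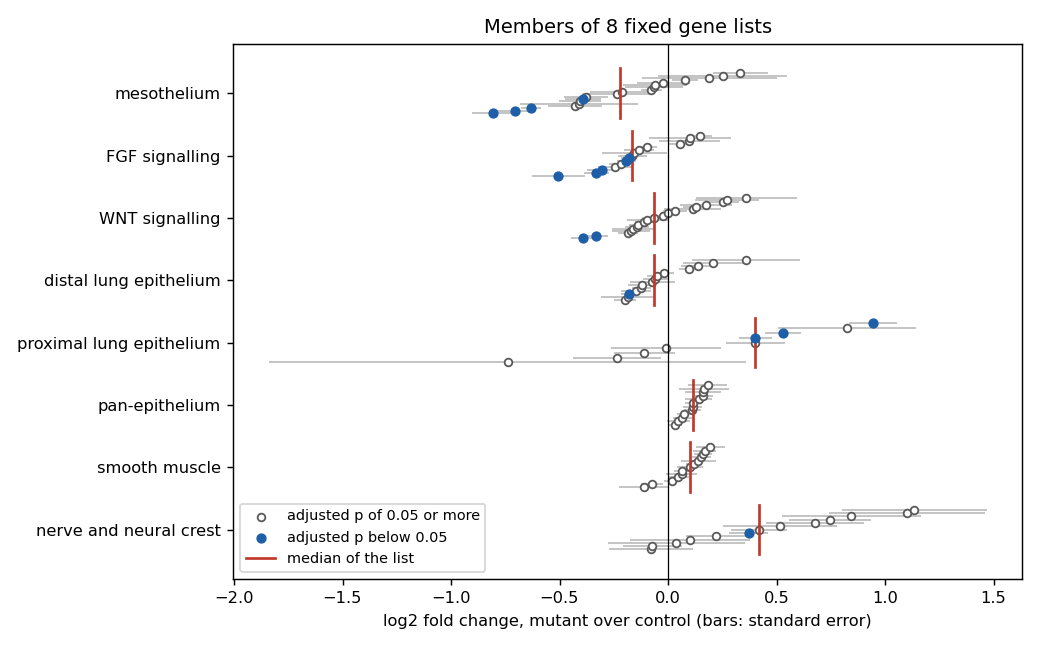
Log2 fold change of mutant over control (x axis) for each tested member of 8 gene lists, with SE bars; filled points passed over all genes tested, open points did not, and the vertical bars mark the medians. The medians are -0.22 for mesothelium, -0.16 for FGF signalling, 0.40 for proximal lung epithelium, 0.12 for pan-epithelium and 0.42 for nerve and neural crest.

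Of the listed contractile, matrix and endothelial genes, 2 rose over all genes tested. Of 13 tested smooth muscle genes 0 passed in edgeR, 5 at an unadjusted p below 0.05, 1 with DESeq2 and 0 with limma-voom; 5 were higher over the list alone. Acta2, smooth muscle actin, measured 504.6 ± 26.8 and 563.8 ± 24.9 CPM (log2 fold change 0.16, SE 0.0406, adjusted p = 0.0558), and Mylk, myosin light chain kinase, 410.0 ± 14.3 and 389.4 ± 32.04 CPM. The smooth muscle list was higher with camera at the preset correlation (adjusted p = 0.00238) but not with an estimated correlation (adjusted p = 0.43). Of 18 tested extracellular matrix genes 1 rose, Bgn, which encodes biglycan (log2 fold change 0.27, SE 0.0535, adjusted p = 0.0282); 2 were higher over the list alone, and camera gave an adjusted p of 0.0115, or adjusted p = 0.601 with an estimated correlation. Of 16 endothelial genes 1 rose, Emcn, which encodes endomucin (log2 fold change 0.19, SE 0.0469, adjusted p = 0.0479); 2 were higher over the list alone, and camera gave an adjusted p of 0.00279, or adjusted p = 0.413 with an estimated correlation. The calls of Bgn and Emcn were lost in 6 of 23 and 13 of 24 alternatives. The matrix list lost its call without control replicate 1 (adjusted p = 0.0671), without control replicate 4 (adjusted p = 0.135) and without mutant replicate 3 (adjusted p = 0.139), with 3.44e-08 to 0.601 over its alternatives. The endothelial list lost its call without control replicate 1 (adjusted p = 0.0564, with 0.000153 to 0.413 over its alternatives).

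The basement membrane, mesenchymal progenitor and transition factor lists each included 1 changed gene. The basement membrane list held Col4a1, Col4a2, Col4a5 and Col4a6 but not Col4a3 and Col4a4, which fell (log2 fold changes -0.86 and -0.96). Lama4, a laminin chain of vessels, rose by 0.25 on the log2 scale (SE 0.048, adjusted p = 0.0174) as the 1 changed gene of 18 tested in the basement membrane list, and 1 passed over the list alone. Wnt2 was the 1 changed gene of 15 tested mesenchymal progenitor genes, with 2 lower over the list alone. Snai2, a transcription factor of mesenchymal cells, had a log2 fold change of -0.15 (SE 0.0343, adjusted p = 0.0317) as the 1 changed gene among 11 tested of the epithelial-mesenchymal transition list, where 3 were lower and 2 higher over the list alone. None of the 3 lists passed with camera (adjusted p = 0.293, 0.137 and 0.778). The calls of Lama4 and Snai2 were lost in 4 and 11 of 24 alternatives.

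Markers of tissues next to the lung were also compared. Of 13 tested nerve and neural crest genes 1 rose, Ret, a receptor of enteric and autonomic neurons (12.9 ± 1.53 to 16.7 ± 1.48 CPM, log2 fold change 0.37, SE 0.0895, adjusted p = 0.0453), and 7 were higher over the list alone. The list had a median log2 fold change of 0.42 and was higher with camera (adjusted p = 4.02e-05), though not with an estimated correlation (adjusted p = 0.25), and the call of Ret was lost in 11 of 24 alternatives. All 8 heart muscle genes had positive log2 fold changes, with 0 passing in edgeR over all genes or over the list alone, 1 at an unadjusted p below 0.05, 1 with DESeq2 and 0 with limma-voom; camera gave an adjusted p of 0.00997, or adjusted p = 0.413 with an estimated correlation. Actc1, cardiac actin, measured 61.0 ± 14.4 and 70.1 ± 10.2 CPM, and Myl4, an atrial myosin light chain, 6.92 ± 1.97 and 8.57 ± 1.31 CPM. All 6 skeletal muscle genes had positive log2 fold changes, with 0 passing by edgeR at either p, by DESeq2, by limma-voom or over the list alone, and camera gave an adjusted p of 0.013, or adjusted p = 0.322 with an estimated correlation. Mylpf and Tnnt3, genes of fast muscle fibres, measured 2.73 ± 0.316 and 1.998 ± 0.257 CPM in control and 3.55 ± 1.11 and 2.42 ± 0.267 CPM in mutant libraries. The heart list lost its call without control replicate 4 (adjusted p = 0.116) and without mutant replicate 1 (adjusted p = 0.0998), with 0.000348 to 0.413 over its alternatives. The skeletal muscle list lost it without mutant replicate 4 (adjusted p = 0.18, with 0.000654 to 0.322 over its alternatives).

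The esophagus, stomach and thymus list held 1 changed gene among 5 tested, Tbx1, a transcription factor of the pharynx, which rose from 28.05 ± 1.93 to 35.5 ± 2.05 CPM (log2 fold change 0.34, SE 0.0611, adjusted p = 0.00852). Hbb-bh1, an embryonic globin, rose from 5.70 ± 1.04 to 9.42 ± 0.92 CPM as the 1 changed gene of 12 red blood cell genes; its reads can be shared with other globins. Mrc1, a macrophage receptor, fell from 30.4 ± 2.44 to 24.9 ± 1.06 CPM as the 1 changed gene of 15 immune genes (adjusted p = 0.0334), a call lost in 10 of 24 alternatives, and that of Hbb-bh1 was lost in 3 of 23. Each of the 3 lists held the same 1 gene over the list alone, and none passed with camera (adjusted p = 0.0555, 0.177 and 0.0682). With fry the adjusted p was 0.0311, 0.299 and 0.0381. In the cartilage, liver, lymphatic and pericyte lists 0 genes passed in edgeR, DESeq2, limma-voom or over the list alone, with 3 cartilage genes and 0 of the others at an unadjusted p below 0.05, and camera gave adjusted p = 0.363, 0.513, 0.394 and 0.874. Control and mutant levels were 138.9 ± 4.35 and 131.5 ± 6.64 CPM for Col2a1 and 65.4 ± 3.05 and 71.5 ± 4.06 CPM for Col9a2 of cartilage, and 11.1 ± 0.985 and 10.9 ± 1.43 CPM for Trf and 3.85 ± 1.39 and 5.47 ± 4.26 CPM for Afp of liver. They were 58.1 ± 3.44 and 61.8 ± 2.49 CPM for Mmrn1 and 56.2 ± 3.44 and 52.5 ± 3.16 CPM for Flt4 of lymphatic vessels, and 333.6 and 320.1 CPM for Notch3 and 213.2 ± 7.15 and 213.3 ± 3.32 CPM for Pdgfrb of pericytes.

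The retinoic acid list and the BMP and TGF-beta list included 1 rise each. Aldh1a1, a retinaldehyde dehydrogenase, rose from 14.5 ± 1.87 to 25.9 ± 2.38 CPM (log2 fold change 0.84, SE 0.0888, adjusted p = 6.18e-05) as the 1 changed gene of 12 in the retinoic acid list, where 2 others were lower over the list alone. It lies on chromosome 19 from 20492715 to 20643465. Its near copy Aldh1a7, with which reads can be shared, also rose (log2 fold change 0.39, adjusted p = 0.00175), and both lie within 20 Mb of Myrf. Nog, which encodes the BMP antagonist noggin, rose from 4.01 ± 0.198 to 5.67 ± 0.222 CPM (log2 fold change 0.50, SE 0.11, adjusted p = 0.029) as the 1 changed gene of 19 in the BMP and TGF-beta list, where 1 was higher and 1 lower over the list alone. The call of Nog was lost in 10 of 24 alternatives, and neither list passed with camera (adjusted p = 0.515 and 0.753).

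The Notch, YAP and TAZ, cell cycle, glycolysis, p53, stress and oligodendrocyte lists held 0 changed genes in edgeR. At an unadjusted p below 0.05 they held 0, 2, 2, 1, 2, 4 and 2, with DESeq2 0, 1, 0, 1, 0, 2 and 1, and with limma-voom 0, 1, 0, 0, 0, 1 and 1. Over the list alone 1 YAP and TAZ gene and 1 stress gene were lower and 2 oligodendrocyte genes higher, and none of the 7 lists passed with camera (adjusted p = 0.548, 0.616, 0.225, 0.394, 0.437, 0.38 and 0.0682). The proliferation genes Top2a and Mki67 had log2 fold changes of 0.00 (SE 0.0353) and 0.04 (SE 0.0367). The highest expressed members of the others had log2 fold changes of -0.06 and -0.02 for Notch3 and Notch1, -0.09 and -0.03 for Arhgef17 and Amotl1, -0.10 and -0.20 for the glycolytic Pkm and Eno1, -0.02 and 0.04 for Plk2 and Mdm2, and 0.13 and -0.07 for Atf4 and Hsph1. Mbp, which encodes myelin basic protein, measured 20.6 ± 1.75 and 24.7 ± 1.07 CPM (adjusted p = 0.0638), and Cnp 18.7 ± 0.533 and 19.7 ± 0.218 CPM.

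Rises and falls were ranked among changed genes with a mean log2 CPM of at least 1, groups that did not overlap and no provisional name. Within these limits the largest rises included, besides Aldh1a1 and Hbb-bh1, the axon guidance receptor gene Robo3 (4.28 ± 0.989 to 8.38 ± 0.911 CPM, log2 fold change 0.98, SE 0.141, adjusted p = 0.00138). They also included Vill, a villin-like gene (31.5 ± 1.68 to 50.7 ± 5.62 CPM, log2 fold change 0.68, SE 0.0758). Ctsh, a cathepsin gene, rose by 0.71 on the log2 scale (SE 0.1, adjusted p = 0.00106) and Wnt4, a WNT ligand, by 0.79 (SE 0.154, adjusted p = 0.0165). Celf3, an RNA-binding protein of neurons, Kcna2, a neuronal potassium channel, and Ccno, which encodes cyclin O of multiciliated cells, rose by 0.81, 0.78 and 0.75. The calls of Wnt4, Celf3, Kcna2 and Ccno were lost in 5, 4, 13 and 3 of 24 alternatives.

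Within the same limits the largest falls included the collagen gene Col4a4 (28.8 ± 2.5 to 14.7 ± 1.11 CPM, log2 fold change -0.96, SE 0.0762, adjusted p = 1.68e-06). These falls also included the collagen genes Col4a3 (-0.86, SE 0.144, adjusted p = 0.0046) and Col6a4 (-0.91, SE 0.165, adjusted p = 0.00895). Pappa2, a protease that cleaves insulin-like growth factor binding proteins, fell from 20.45 ± 1.41 to 10.95 ± 0.982 CPM (log2 fold change -0.89, SE 0.0806, adjusted p = 6.95e-06). The homeobox genes Hoxb8 and Hoxa7 had log2 fold changes of -0.84 (SE 0.0909, adjusted p = 6.18e-05) and -0.83 (SE 0.153, adjusted p = 0.00996). The others were mt-Nd6, a mitochondrial gene of the complex I subunit family (-1.10, SE 0.184), Wt1os, the antisense transcript of Wt1 (-0.91, SE 0.201), Tdo2, a tryptophan dioxygenase gene (-0.81, SE 0.164), and the long noncoding RNA Lrp8os2 (-0.81, SE 0.16). Calls were lost in 1 of 24 alternatives for Col4a3, 3 for Col6a4, 4 for Hoxa7, 7 for mt-Nd6, 10 for Wt1os, 5 for Tdo2 and 6 for Lrp8os2.

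Transcripts of the sex chromosomes differed between libraries and were not balanced between the groups. Xist, which is expressed from the inactive X chromosome of females, measured 869 and 863 CPM in control replicates 2 and 3, where the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 0 and 0.0562 CPM. In mutant replicates 1 and 2, Xist measured 0.596 and 0.370 CPM and the Y-linked genes 133.8 and 143.8 CPM. The other 4 libraries, control replicates 1 and 4 and mutant replicates 3 and 4, had Xist between 350.1 and 402.6 CPM together with Y-linked genes between 64.2 and 76.2 CPM. In these 4 libraries the presence of both argues against material from 1 embryo alone. The number n = 4 counts libraries, since the labels do not give the number of embryos in a library. Of the 236 changed genes, 9 lay on the X chromosome, Bgn among them, and the other 227 were autosomal.

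**Figure D3:**
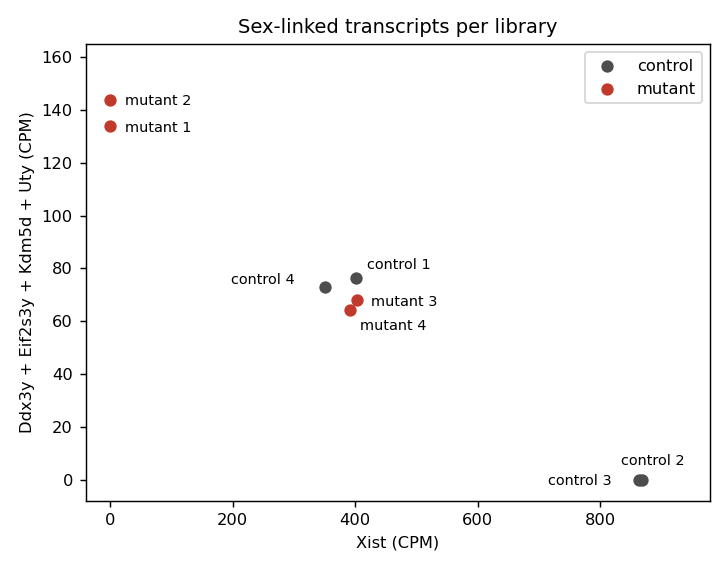
Summed CPM of 4 Y-linked genes (y axis) against those of Xist (x axis) in each of the 8 libraries, labelled by group and replicate. Control replicates 2 and 3 lie at 863 CPM or more of Xist and almost no Y-linked counts, mutant replicates 1 and 2 at the opposite corner, and the other 4 libraries have both.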

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

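No tests in this part were chosen after the result was seen, although most of the genes they cover were named for their change. Single libraries stood apart from the other 3 of their group in 10 of 146 sets of values, where chance alone picks out about 1 in 20. Control replicate 2 accounted for 4 of them: Wt1 was 17.5 CPM there and 20.4 to 20.7 CPM in the other controls, Etv5 395 CPM against 378 to 381, Emcn 44.4 CPM against 48.9 to 49.5, and Lef1 42.1 CPM against 48.5 to 49.4. Mutant replicate 2, the deepest library, had Robo3 at 9.73 CPM against 7.77 to 8.05 and Sox2 at 17 CPM against 20.5 to 20.9 in the other mutants. The other values were mt-Nd6 at 6.19 CPM in mutant replicate 4 against 4.39 to 4.61, Mmrn1 at 63.2 CPM in control replicate 3 against 56.0 to 57.0, and Col9a2 at 65.5 CPM in mutant replicate 1 against 73.4 to 73.8. The total of control replicate 1 was 19 M counts (19032389), against 17799899 to 17847958 counts in the other controls.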

How the results depend on the processing

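The alternatives with the linear Y-linked level as a covariate, the 4 libraries with both Xist and Y-linked counts, and thinned libraries were chosen only after the data were seen; the others were fixed before. Myrf stayed lower and past the threshold in every alternative run, with log2 fold changes from -0.397 to -0.339 when single libraries were left out. The 236 changed genes gave 791 changed (340 higher, 451 lower) with no low-count filter, where 29900 genes were tested, 380 (140 higher, 240 lower) with DESeq2 and 142 (56 higher, 86 lower) without robust estimation. They gave 97 (53 higher, 44 lower) with the log2 level of Y-linked genes as a covariate, 96 (44 higher, 52 lower) with 1 surrogate variable, and 68 (39 higher, 29 lower) with the linear Y-linked level, 52 of them shared with the 236. The 4 libraries with both Xist and Y-linked counts gave 87 (55 higher, 32 lower), 44 of them shared, with fewer samples. Thinning to the smallest total gave 159 changed with 96 lower. At adjusted p below 0.01 there were 59 genes, and 60 with a change of at least 1.5-fold, fewer by definition since both are subsets of the 236. For the counts from the other alternatives, the cause was not tested. Leaving out single libraries gave 96 to 479 changed, 48 to 139 higher, 47 to 340 lower and 8 to 13 lists. The extremes of changed genes came without control replicate 3 and without mutant replicate 4; the count was 100 without control replicate 1, 121 without control replicate 2 and 118 without mutant replicate 2. Lower genes were also 223 without control replicate 4 and 85 without mutant replicate 1. The other scalings, limma-voom, the filter at 1 CPM and the removal of X and Y or red blood cell genes moved the counts by less than 1.5 times.

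Of the lists, 10 passed with camera at the preset correlation and 0 with an estimated correlation, where 4 had an unadjusted p below 0.05. Fry passed 8, including 5 of the 10. Camera calls not passed by fry were smooth muscle (fry adjusted p = 0.141), endothelium (0.139), heart muscle (0.208), skeletal muscle (0.141) and extracellular matrix (0.386). Lists passed by fry alone were immune cells (0.0381), esophagus, stomach and thymus (0.0311) and oligodendrocyte genes (0.0381). The pericyte list, which did not pass (adjusted p = 0.874, direction lower), passed in the opposite direction with the linear Y-linked level as a covariate (adjusted p = 0.0491) and in the 4 libraries with both Xist and Y-linked counts (adjusted p = 0.027), with 0.027 to 0.957 over its alternatives; the cause was not tested. For single lists, 23 alternative results lost a call and 15 gained one, and for single named genes 160 lost a call and 13 gained one. Upk3b, Wt1, Sox2, Aldh1a1, Lef1, Wnt2, Col4a4, Hoxb8, Pappa2, Robo3, Tbx1, Ctsh and Vill passed in all 24 alternatives run for them. Medians, means and tests differed in sign for the pericyte, retinoic acid, BMP and TGF-beta, YAP and TAZ, and epithelial-mesenchymal transition lists, none of which passed.

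Replicate numbers are shared between the groups. Deviations from the group means correlated between same-numbered samples by 0.0125 to 0.181, not above 0.1 in every pair. Between different-numbered samples they correlated by -0.171 to 0.133, and 5 of 8 samples correlated best with their own number. The labels do not say that the numbers pair the samples, so no pairing was used in the main fit. These correlations do not exclude a pairing. With a replicate block the fit called 541 genes (220 higher, 321 lower), 230 of them shared with the 236. At the depth of these libraries, a change in a gene near 0.169 CPM, 3 counts in the smallest library, was not detectable.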

Other observations

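Chosen only after the results were seen were the tests of the gene families and of the single genes first named here, the test of the epithelial share, the marker test without Nkain4 and the linear Y-linked covariate. Hox genes, which pattern the body axis, included 3 that fell among 16 tested, and the median of the 16 log2 fold changes was -0.25, or between -0.25 and -0.24 under the 3 other scalings. The 3 were Hoxb8, Hoxa7 and Hoxa6 (5.91 ± 0.795 to 3.68 ± 0.394 CPM, log2 fold change -0.67, SE 0.131, adjusted p = 0.0152), while Hoxb5 measured 107.8 ± 7.86 and 109.3 ± 6.4 CPM (adjusted p = 0.92). Chance is not excluded for the family: 2 of the 35 splits of the 8 libraries into 4 and 4 gave a camera p as small as the real one (1.73e-08, smallest other 2.52e-09, exact permutation over all splits), a p that is 0.0387 with an estimated correlation. Of 76 ribosomal protein genes 62 had negative log2 fold changes with a median of -0.06, negative under the other scalings too, and 8 fell, or 5 with library size alone. Chance is not excluded for them either, with 3 of the 35 splits as small (real 1.7e-09, smallest other 2.72e-16, exact permutation), a p that is 0.155 with an estimated correlation, and reads of such genes can be shared with pseudogenes.

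Collagen IV genes did not move as 1 family under any of the 4 scalings. Col4a3 and Col4a4, neighbours on chromosome 1 whose chains assemble with that of Col4a5, fell, while Col4a5 had a log2 fold change of 0.03 (SE 0.0628, adjusted p = 0.876), Col4a1 measured 1174 ± 107.6 and 1154 ± 90.2 CPM and Col4a2 656.6 ± 66.2 and 636.8 ± 46.3 CPM (adjusted p = 0.929 and 0.871). The ephrin receptor gene Epha3 fell from 70.8 ± 3.86 to 51.0 ± 2.69 CPM (log2 fold change -0.47, SE 0.0496, adjusted p = 5.5e-05). Of 45 semaphorin, netrin and Slit family genes 4 fell, or 3 with upper-quartile scaling or library size alone, among them Sema3a (-0.33, adjusted p = 0.00282), Sema3d (-0.54, adjusted p = 0.00536) and Unc5b (-0.24, adjusted p = 0.00443), and 1 rose, Robo3. The family as a whole did not stand apart: its median was -0.01, 24 of 45 log2 fold changes were negative, and 22 of the 35 splits gave a camera p as small as the real one (0.577, smallest other 0.0125, exact permutation). The imprinted genes Peg10 and Asb4, both on chromosome 6, fell from 139.8 ± 6.55 to 101.1 ± 9.02 CPM (adjusted p = 0.000553) and from 21.7 ± 2.41 to 14.5 ± 2.32 CPM (adjusted p = 0.0128). Foxa1, a transcription factor of the lung epithelium, rose from 67.8 ± 2.09 to 81.0 ± 3.49 CPM (adjusted p = 0.00417), Cftr, the chloride channel gene, from 15.5 ± 0.81 to 19.7 ± 0.832 CPM (adjusted p = 0.0162), and Bmp3 by 0.62 on the log2 scale (adjusted p = 0.000368).

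Chance was argued against for the number of changed genes, 236. Among all 35 splits, 1, the real split, gave as many changed, higher or lower genes, and the highest other gave 7. That share is the smallest 35 splits can give, and every other split mixed control and mutant libraries on both sides. Unequal sex of the embryos was argued against as the whole source, since with the linear Y-linked level as a covariate the log2 fold changes of the 227 changed autosomal genes kept a median of 0.974 of their size, with a lower quartile of 0.815. The count fell to 68 under that covariate while the SE of those genes grew by a median of 1.32 times, so the calls that ended are not shown to be free of sex. Strain variants carried along with the Myrf allele cannot be told apart from an effect of Myrf for the 6 changed genes of 320 tested within 20 Mb of it, Aldh1a1 among them: the odds ratio was 1.27, and its interval of 0.458 to 2.84 leaves the matter open (exact Fisher p = 0.483). An effect of the mutation stays open as a hypothesis, as do differences in litter or dissection. In the 4 libraries with both Xist (350.1 to 402.6 CPM) and Y-linked counts (64.2 to 76.2 CPM), these levels argue against material from 1 embryo alone. The labels do not give the number of embryos, and the spread between libraries could be smaller than that between embryos.

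For the mesothelium list as a whole chance is not excluded: 3 of the 35 splits gave a camera p as small as the real one (1.08e-05, smallest other 9.96e-07, exact permutation over all splits), and the other 2 exchanged mutant replicate 1 with a control. Upk3b, Wt1, Gpm6a and Lrrn4 are among the 236 changed genes. The split test of that number does not show which single genes differ. A loss of mesothelial cells that lowers every marker alike was argued against, because the log2 fold changes of the 8 restricted markers, of which Upk3b, Wt1 and Lrrn4 passed and Msln was positive, differed from each other (Cochran Q 84.8, p = 1.46e-15 from an approximate, not an exact, test) and Nkain4 lay wholly above their common log2 fold change of -0.40. Without Nkain4 that p was 0.00277, likewise approximate and not exact. Fewer mesothelial cells with some markers also made by other cells, and lower expression within mesothelial cells, both stay open as hypotheses.

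For the proximal epithelial list, 1 of the 35 splits, the real one, gave as small a camera p (0.000165, smallest other 0.000477, exact permutation over all splits), and its call is lost with an estimated correlation (adjusted p = 0.26). That share is the smallest 35 splits can give, so it leaves chance open for a list singled out among 32. As a test of a larger share of epithelium, the pan-epithelium list had a median log2 fold change of 0.115 and an upper quartile of 0.16. Both lay below the lowest lower 95% limit of the changed proximal genes, 0.252. This test cannot decide the question, since it used only the 3 proximal genes that passed. It left out the 6 that did not, 4 of them with negative log2 fold changes. The bounds of that test were set after these values were seen and replaced earlier bounds that the values met on neither side. A larger share of epithelium, a larger share of proximal airway and higher expression in the same cells stay open as hypotheses.

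Over all 32 lists chance is not excluded for the number that passed: 2 of the 35 splits gave as many as the real one (10, highest other 11).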
